A study of Mus musculus with 12 samples.

How the data were processed

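The series holds 12 RNA sequencing libraries of WT and Ddx55-KO naive CD4+ T cells at 0, 8 and 24 h of stimulation, 2 per group in 6 groups. Per the labels, total RNA was depleted of ribosomal RNA and read as stranded, paired reads of 150 bases; the authors name fastp 0.12.4, STAR 2.7.1a and the mm10 build without their roles or parameters. The 2 deposited tables hold raw counts, 1 per gene and 1 per repeat locus, in a column for each library; the values are whole numbers with no normalization. The counter, the annotation, the handling of reads with several matches and the use of molecular identifiers are not given in the sources used here. All 12 columns were matched to the labels by genotype, replicate number and time.

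The gene table has 54232 genes, and 54079 matched a symbol of the GRCm38 annotation. Genes were filtered with edgeR's filterByExpr by group (count of at least 10, total of at least 15), which kept 15679 and removed 38553. A single quasi-likelihood fit (edgeR 4.0.16 in R 4.3.3, TMM factors, robust) had 1 mean per group and 6 residual degrees of freedom. Its 8 contrasts were KO against WT at 0, 8 and 24 h, WT at 8 h and 24 h against 0 h, the change of the KO effect from 0 h to 8 h and to 24 h, and the KO effect averaged over times. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene counts per library, from 16810375 to 19126498, set the counting precision, and with 2 libraries per group the spread is estimated from all groups together.

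The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Ddx55 in every comparison. For each KO against WT contrast it takes the 10 rising and 10 falling genes with the largest fold change among those past the threshold, with a mean CPM of at least 5 and no overlap between the libraries of the 2 groups. It takes 5 per direction for activation and for the changes of the KO effect (there without the overlap condition), up to 3 members per list with the smallest p, and 5 repeat subfamilies per direction with a mean count of at least 100. Predicted genes and clone names were skipped, between 0 and 3 per comparison and direction.

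Lists were tested with camera (limma 3.58.1, preset correlation of 0.01, on log2 CPM with a prior count of 2), adjusted over 30 lists and 8 contrasts (240 tests), again with an estimated correlation, and with fry. With the preset correlation 14, 21 and 24 of 30 lists passed for KO against WT at 0, 8 and 24 h; 0 of the 240 camera tests passed with an estimated correlation, where 50 had an unadjusted p under 0.05, and fry passed 13, 16 and 25 lists for KO against WT. The 30 lists are interferon-stimulated genes, p53 target genes, pro-apoptotic genes, anti-apoptotic genes, ribosome biogenesis factors, DEAD-box and DEAH-box helicases other than Ddx55, cytosolic ribosomal proteins, T cell receptor early response genes, T cell activation receptors and transporters, cytokines and chemokines, naive and quiescence genes, T helper lineage genes, memory-like T cell genes, S phase genes, G2/M genes, replication-dependent histones, glycolysis genes, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, cholesterol synthesis genes, ATF4 and amino acid response genes, unfolded protein response genes, repeat silencing and restriction factors, genes next to Ddx55, and markers of B cells, myeloid cells, CD8 T and NK cells, regulatory T cells, erythroid cells and platelets, and stromal and endothelial cells. A further 4 lists, of basophil and mast cell genes, neutrophil and granulocyte progenitor genes, eosinophil genes and T cell identity genes, were written after the values were seen.

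The repeat table has 3156417 loci, and 3009836 belong to the LINE, SINE, LTR and DNA classes; 622209 of these had a count. Counts were summed per subfamily, 1167 subfamilies passed the filter, and library sizes and TMM factors came from the gene table. Loci were called exonic, intronic or intergenic by the annotation, and held 39.9%, 40.0% and 20.1% of repeat counts. Repeat counts relative to gene counts were compared with an exact permutation test within times.

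The procedure was tested on simulated data with the size, depth and spread of these libraries, in which 200 genes were changed. For KO against WT at 24 h it recovered 33.8% of genes changed 1.5-fold and 86.4% of those changed 2-fold, and for the change of the KO effect 10.3% and 69.7%. Over 12 simulated draws the false share of calls averaged 7.1% for KO against WT at 24 h and 8.1% for the change of the KO effect from 0 h to 24 h (from 2.1% to 8.8% and from 4.2% to 14.5% between draws). Both averages lie above the nominal 5%, so the adjusted p-values are somewhat lenient in this setting. In the data 6041 genes passed at 24 h, so the simulated shares need not carry over to that comparison. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter of CPM of at least 1 in 2 libraries, fits of the 4 libraries of a time, the replicate number as an added term, and leaving out each library; for repeats also their own totals and factors, and loci with fewer than 10 counts left out. Chosen after seeing the data were fits of 9 libraries without the 3 KO libraries of either number, and repeat counts from exonic, intronic or intergenic loci alone. Repeat classes other than the 4 were left out of the tests.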

Results

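Total RNA was measured in wild-type (WT) and Ddx55-knockout (KO) naive CD4+ T cells of the mouse. Ddx55 is an RNA helicase of the DEAD-box family. The cells were taken before stimulation (0 h), or after 8 h or 24 h on plates coated with antibodies to CD3 (5 ug/ml) and CD28 (2.5 ug/ml). These engage the T cell receptor complex and a costimulatory receptor. Each of the 6 groups held 2 libraries, 12 in all. Gene counts per library lay between 16810375 and 19126498, and counts at repeat loci of the LINE, SINE, LTR and DNA classes between 1135872 and 1872809. Of the variance of the 2000 most variable genes, the first principal component carried 56.8% and the second 18.8%. Values below are CPM scaled with TMM factors, as mean ± SD (n = 2), or log2 fold changes ± SE from the edgeR fit. Rankings by size of change cover only the genes that the naming rule admits. The labels do not say whether the libraries of a group came from separate animals, so every p-value measures only the spread between these samples.

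Ddx55 RNA was lower in KO cells at every time, and part of it remained. Ddx55 (ENSMUSG00000029389, GRCm38 chromosome 5, 124552864 to 124569660) stood at 48.2 ± 4.14 CPM in WT and 19.2 ± 0.38 CPM in KO cells at 0 h, which is 39.9% of the WT level. At 8 h it stood at 66.4 ± 3.28 in WT and 17.5 ± 0.60 in KO cells (26.4% of WT), and at 24 h at 54.0 ± 1.66 and 14.6 ± 0.18 (27.0%). Its log2 fold change was -1.33 ± 0.104 at 0 h (adjusted p = 9.48e-06), -1.92 ± 0.106 at 8 h (adjusted p = 1.17e-07) and -1.89 ± 0.107 at 24 h (adjusted p = 5.5e-09). In WT cells Ddx55 rose by 8 h (0.46 ± 0.10, adjusted p = 0.000911), and its value at 24 h against 0 h was 0.16 ± 0.10 (adjusted p = 0.161). Which exons the knockout removes is not given in the sources used here, and the counts are per gene.

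**Figure D1:**
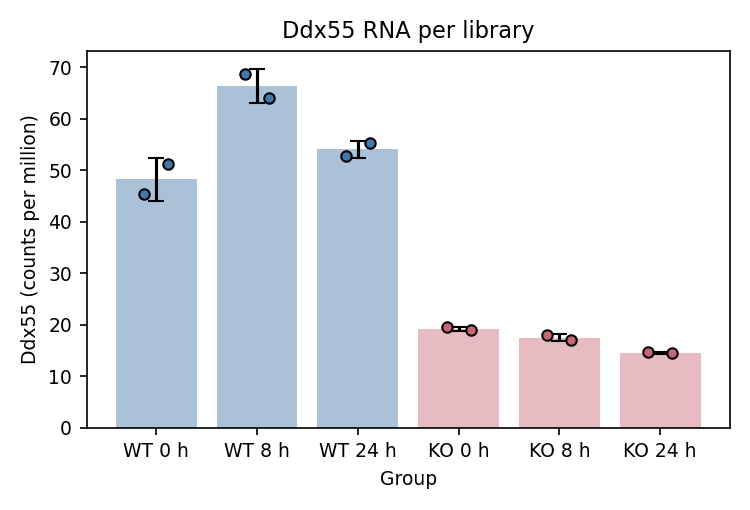
Ddx55 RNA in CPM (y axis) in each of the 6 groups (x axis); points are libraries, bars group means and whiskers the SD (n = 2). The KO groups stand at 39.9%, 26.4% and 27.0% of WT at 0, 8 and 24 h.

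The WT time course asks how naive CD4+ T cells respond to stimulation. After 8 h, WT cells held more RNA of activation genes: Il2ra, the high-affinity IL-2 receptor chain, rose by 8.00 ± 0.16 on the log2 scale, Tnfrsf9 by 5.98 ± 0.16 and Pdcd1 by 5.80 ± 0.16. Of the 23 activation receptors and transporters tested, 19 rose and 1 fell (camera adjusted p = 3.95e-09, and 0.136 with an estimated correlation). Ribosome biogenesis factors moved together, with 70 of 72 higher (median 1.98; camera adjusted p = 9.01e-25, and 0.271 with an estimated correlation), among them Nop2 (2.65 ± 0.11) and Rrs1 (2.49 ± 0.10). Naive and quiescence genes went the other way, with 24 of 30 lower and 4 higher (median -2.21; adjusted p = 0.348 with an estimated correlation), among them Il7r (-3.04 ± 0.12). Of 75 interferon-stimulated genes 59 fell and 4 rose (median -1.77; adjusted p = 0.43 with an estimated correlation), with Ddx58, which encodes the RNA sensor RIG-I, at -3.39 ± 0.14. By the size of the change, Chst2 (413.9 ± 24.5 CPM against 0.684 ± 0.286), Xcl1, Bdh2, Spin4 and Npas4 led the genes that rose. Slc16a5, Lrrc75b, Fosb, Jun and Mpo, the last a neutrophil and granulocyte progenitor gene, led those that fell. Jun, an AP-1 subunit, stood at 844.4 ± 459 CPM and Fosb at 454.8 ± 477 CPM in WT cells at 0 h, so that the libraries of that group differed widely in these genes. At 8 h S phase genes went both ways, with 24 of 46 higher and 10 lower (median 0.47; 24 and 11 adjusted over the list alone; adjusted p = 0.514 with an estimated correlation). Of 41 G2/M genes 5 were higher and 22 lower (median -1.26; adjusted p = 0.733 with an estimated correlation). In all, 9709 of 15679 genes passed an adjusted p of 0.05 in edgeR at 8 h against 0 h, 4443 higher and 5266 lower.

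After 24 h, cell cycle genes were mostly higher. All 46 S phase genes were higher than at 0 h (median 3.56; camera adjusted p = 3.7e-21, and 0.0634 with an estimated correlation), among them the replication factors Mcm5 (4.19 ± 0.10) and Mcm10 (7.41 ± 0.19). Of 41 G2/M genes 39 rose and 1 fell (median 4.58; adjusted p = 0.306 with an estimated correlation), and of 21 replication-dependent histones 14 rose and 2 fell (median 2.25; adjusted p = 0.305 with an estimated correlation). Cholesterol synthesis genes rose in 23 of 24 cases, with Sqle at 3.17 ± 0.13 and Idi1 at 4.45 ± 0.18 (adjusted p = 0.281 with an estimated correlation). Glycolysis genes rose in 16 of 22 cases and fell in 4, with Hk2 at 6.88 ± 0.21 (adjusted p = 0.306 with an estimated correlation), and 56 of 65 nuclear-encoded oxidative phosphorylation genes rose while 2 fell (adjusted p = 0.523 with an estimated correlation). Il2 reached 177.2 ± 10.3 CPM from 0.209 ± 0.045, and Bcat1 reached 221.2 ± 4.77 from 0.895 ± 0.096. The median of all genes moved by -0.146 from 0 h to 8 h and by -0.088 from 0 h to 24 h, and from 0 h to 8 h by -0.071 with RLE size factors. Wnt10b and Hist1h3c, with 3 and 1 counts over the WT 0 h libraries, stood at 24.9 ± 5.95 and 13.4 ± 0.53 CPM at 24 h, and Spin4 at 30.8 ± 6.54 CPM. Igha, Mpo, Fosb, Ifi213 and Ampd1 led the genes that fell, with Ifi213 going from 304.1 ± 44.7 to 2.49 ± 0.77 CPM. Igha is an immunoglobulin gene and Mpo a neutrophil and granulocyte progenitor gene. Of 18 such progenitor genes, a list written after the values were seen, 9 fell and 1 rose in WT cells by 24 h (median -4.24). Whether these falls came from T cells or from other cells in the libraries was not tested. In all, 10434 genes passed the threshold, 5173 higher and 5261 lower.

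The comparison of KO with WT cells before stimulation asks what differs in the starting population. At 0 h most G2/M genes, and part of the S phase, p53 target and granulocyte genes, were higher in KO cells. Each library pools all cells of a sample. The values therefore do not show whether T cells or other cells, such as those with the granulocyte genes, held the cell cycle RNA. Of 41 G2/M genes 34 were higher in KO cells (median log2 1.96; 37 higher and 1 lower when adjusted over the list alone), among them the mitotic kinase gene Aurkb (2.41 ± 0.28) and Ckap2l (2.80 ± 0.32); camera gave an adjusted p of 1.77e-29, and 0.176 with an estimated correlation. Of 46 S phase genes 20 were higher (median 0.47; 29 adjusted over the list alone), with Mcm10 at 5.84 ± 0.39 against 0.892 ± 0.325 CPM (adjusted p = 0.0857 with an estimated correlation). Of 30 p53 target genes 10 were higher and 1 lower (median 0.36; 13 and 2 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Among genes that the naming rule admits (mean CPM of at least 5), the p53 targets Psrc1 (21.5 ± 1.10 CPM in KO, 0.836 ± 0.18 in WT) and Phlda3 (13.4 ± 0.07 against 0.569 ± 0.387) stood first by size of change. The neutrophil and granulocyte progenitor genes Ms4a3, S100a8, S100a9, Prtn3 and Cebpa followed, with Cd34, Hp and Anxa1. Prtn3, a serine protease of neutrophil granules, stood at 78.0 ± 22.1 CPM in KO and 5.04 ± 4.74 CPM in WT cells.

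Interferon-stimulated genes were also higher in KO cells at 0 h, 26 of 75 (median 0.49; 40 adjusted over the list alone), among them Mx2 (1.90 ± 0.19) and Ifi44 (2.08 ± 0.26); the adjusted p was 0.299 with an estimated correlation. Of 19 memory-like T cell genes 9 were higher (median 0.68; 13 adjusted over the list alone), with Il2rb at 1.06 ± 0.11 and Nkg7 at 2.48 ± 0.30 (adjusted p = 0.176 with an estimated correlation). Markers of other cells were higher beside these groups: 8 of 18 myeloid markers (adjusted p = 0.264 with an estimated correlation) and 6 of 12 CD8 T and NK cell markers (adjusted p = 0.283 with an estimated correlation). The summed CPM of the 18 tested neutrophil and granulocyte progenitor genes was 573.2 and 569.1 in the KO libraries at 0 h, and 77.3 and 27.5 in the WT libraries. The 19 T cell identity genes had a median of -0.10 at 0 h; this list and the granulocyte lists were written after the values were seen. Among genes lower in KO cells stood Zfp69 (2.88 ± 0.96 against 20.2 ± 10.7 CPM), Crmp1, Itga7, Rnf32, Unc5a, Ttc28, Ddr1, Sntb1 and Wfikkn2, next to Ddx55 itself. In all, 893 genes passed the threshold, 726 higher and 167 lower in KO cells. The count was 464 in a fit of the 4 libraries of that time, 1895 without the 3 KO libraries numbered 2 (an alternative chosen after seeing the data), 522 without WT 0 h replicate 1 and 348 without WT 0 h replicate 2.

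At 8 h the p53 targets were the group most shifted towards higher levels in KO cells by the number of its members that passed. Of 30 p53 target genes 19 were higher (median 1.07; 22 higher and 1 lower adjusted over the list alone), among them Psrc1 (145.2 ± 8.39 against 23.6 ± 3.43 CPM), Polk (1.56 ± 0.10) and Zmat3 (1.60 ± 0.11); camera gave an adjusted p of 1.06e-18, and 0.0634 with an estimated correlation. The cytokine gene Ccl1 (9.64 ± 1.38 against 1.37 ± 0.38 CPM) and the costimulatory ligand gene Tnfsf4 (53.2 ± 1.44 against 8.06 ± 2.36 CPM) were higher, and 6 of 22 cytokines and chemokines passed (13 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation). S phase genes were lower at 8 h in 8 of 46 cases (median -0.30; 22 lower and 1 higher adjusted over the list alone), with Mcm2 at -0.55 ± 0.08 (adjusted p = 0.168 with an estimated correlation). G2/M genes leaned the other way at 8 h, with a median of 0.75. In edgeR 0 of the 41 passed (16 higher and 1 lower at an unadjusted p under 0.05; 10 and 1 adjusted over the list alone), and in DESeq2 8 were higher and 1 lower (adjusted p = 0.43 with an estimated correlation). Interferon-stimulated genes were higher in 10 of 75 cases (median 0.42; 24 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation). Memory-like T cell genes were higher in 6 of 19 (median 0.89; 14 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). Glycolysis genes were lower in 6 of 22 cases, with Tpi1 at 57.5 ± 21.5 against 112.6 ± 3.93 CPM (13 lower and 1 higher adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Unfolded protein response genes were lower in 4 of 20 cases and cholesterol synthesis genes in 3 of 24 (12 and 11 adjusted over the list alone). With an estimated correlation their adjusted p was 0.0981 and 0.259. The other genes that led by size were Plac8, Serpina3g, Muc13, Adgrg1, Lilr4b, Penk and Rgs12 among those higher, and Lpar5, Pcgf2, Zdhhc23, Igsf8, Dhrs13, Pdxk, Gk and Cdca7l among those lower. The summed CPM of the 18 tested basophil and mast cell genes, a list written after the values were seen, was 215.2 and 617.3 in the KO and 32.1 and 24.4 in the WT libraries at 8 h. In all, 415 genes passed the threshold, 298 higher and 117 lower. The count was 103 without WT 8 h replicate 1, 113 without WT 8 h replicate 2, 175 without KO 8 h replicate 2, 641 in DESeq2, 862 with no filter on low counts and 1215 without the 3 KO libraries numbered 1, the last chosen after seeing the data.

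At 24 h cell cycle genes were lower in KO cells. All 46 S phase genes were lower in KO than in WT cells (median -2.80; 46 adjusted over the list alone), among them Mcm10 (7.53 ± 0.21 against 153.1 ± 11.6 CPM) and Cdc6 (7.46 ± 1.17 against 151.3 ± 5.20), which load and activate the replicative helicase; camera gave an adjusted p of 1.77e-36, and 0.0634 with an estimated correlation. All 41 G2/M genes were lower (median -3.01; 41 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation), as were 17 of 21 replication-dependent histones (median -3.42; 18 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation). Cyclin E1 (Ccne1) stood at 5.10 ± 0.96 against 108.4 ± 2.93 CPM. Hist1h3c, Clspn, Pclaf, Lrr1, Fancd2, Kntc1 and Tcf19 completed the 10 genes that were lower by the most among those that the naming rule admits. Fancd2 of the DNA crosslink repair pathway stood at 3.31 ± 0.28 against 67.0 ± 8.87 CPM.

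At 24 h cholesterol synthesis genes, most glycolysis genes and part of the oxidative phosphorylation genes were lower in KO cells. All 24 cholesterol synthesis genes were lower (median -1.68), and 18 of 22 glycolysis genes were lower (median -1.17), with Pgam1 at -1.41 ± 0.11. Adjusted over the list alone, 24 and 18 were lower. With an estimated correlation the adjusted p was 0.168 for cholesterol synthesis genes and 0.138 for glycolysis genes. Of 65 nuclear-encoded oxidative phosphorylation genes 31 were lower and 1 higher (median -0.28; 32 and 1 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation). Ribosome biogenesis factors, the process in which relatives of Ddx55 act, were lower in 18 of 72 cases and higher in 2 (median -0.15; 13 and 1 adjusted over the list alone; adjusted p = 0.767 with an estimated correlation), with Lyar at -0.99 ± 0.11. Cytosolic ribosomal proteins were higher in 56 of 78 cases (median 0.44; 62 adjusted over the list alone; adjusted p = 0.556 with an estimated correlation), with Rps7 at 0.80 ± 0.12.

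The p53 target genes and many cytokine genes were higher in KO cells at 24 h. Of 30 p53 target genes 26 were higher and 2 lower (median 1.66, with 26 and 2 adjusted over the list alone; adjusted p = 0.0884 with an estimated correlation), with Psrc1 at 3.76 ± 0.14 and Zmat3 at 2.35 ± 0.12. The death genes Fas (2.60 ± 0.14), Bbc3 (3.18 ± 0.20) and Bax (1.40 ± 0.12) were higher, and of 23 pro-apoptotic genes 7 were higher and 8 lower (median -0.05 and mean 0.33, opposite in sign, with 7 and 9 adjusted over the list alone; adjusted p = 0.885 with an estimated correlation). Of 22 cytokines and chemokines 14 were higher, with Ifng at 3.54 ± 0.41 and Ccl1 at 2.88 ± 0.30 (16 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). Of 12 CD8 T and NK cell markers 7 were higher (median 2.39; 8 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation). T cell receptor early response genes were higher in 17 of 30 cases and lower in 1, with Nfkb2 at 1.34 ± 0.11 (17 and 1 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation). T helper lineage genes were higher in 11 of 19 cases, with Gata3 at 1.83 ± 0.18 (12 adjusted over the list alone; adjusted p = 0.0981 with an estimated correlation). Of 33 ATF4 and amino acid response genes 16 were higher and 5 lower, with Ddit3 at 2.69 ± 0.12 (19 and 5 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation).

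By size of change, basophil, mast cell and other granulocyte genes led those higher in KO cells at 24 h among genes that the naming rule admits. Mcpt8, a basophil protease, stood at 141.3 ± 119 CPM in KO and 1.76 ± 0.20 CPM in WT cells, and Prss34 at 94.6 ± 71.2 against 0.891 ± 0.041. Cpa3, Fcer1a, Ms4a2, Alox5, Prg2, Epx, Ctsg and Mpo completed these 10 genes, and Mpo, with 3 counts over the WT 24 h libraries, stood at 10.1 ± 8.20 CPM in KO cells. The SDs of these genes are close to their means, since the summed CPM of the basophil and mast cell genes was 274.4 in KO 24 h replicate 1 and 968.5 in replicate 2, against 27.1 and 28.0 in WT. Beside the lower cell cycle genes, the 19 T cell identity genes had a median of 0.21, with 7 higher and 2 lower. In all, 6041 of 15679 genes passed the threshold in edgeR, 2799 higher and 3242 lower. With the 3 KO libraries numbered 1 left out 5739 passed (5201 of them shared), and with those numbered 2 left out 5720 (5194 shared), a pair of alternatives chosen after seeing the data.

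**Figure D2:**
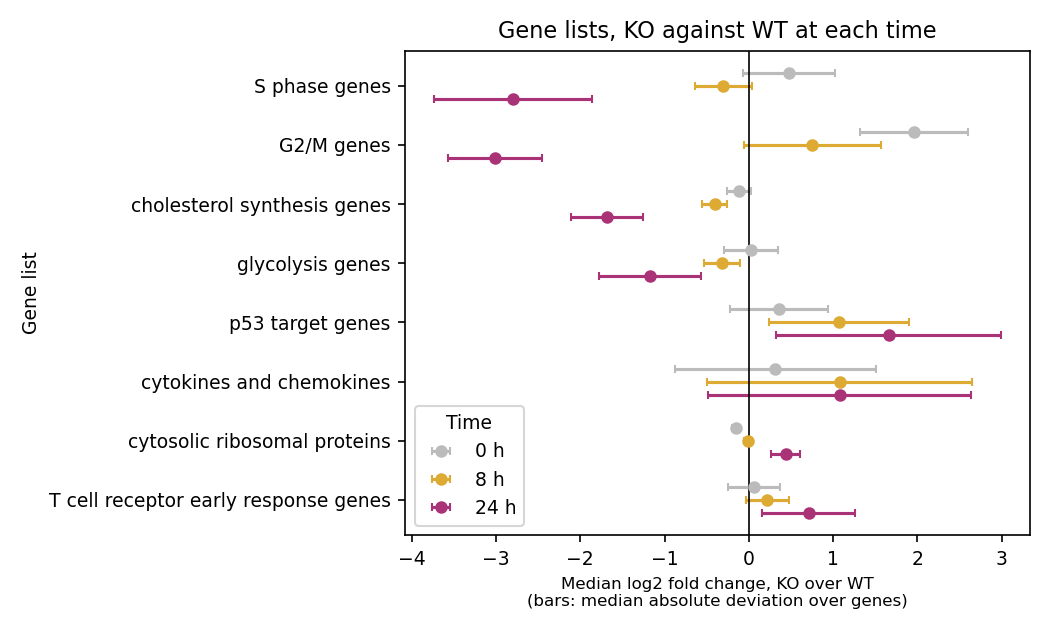
Median log2 fold change of KO over WT (x axis) of 8 gene lists (y axis) at 0, 8 and 24 h; whiskers show the median absolute deviation over the genes of a list. S phase genes go from 0.47 at 0 h to -0.30 at 8 h and -2.80 at 24 h, and p53 target genes from 0.36 to 1.07 and 1.66.

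**Figure D3:**
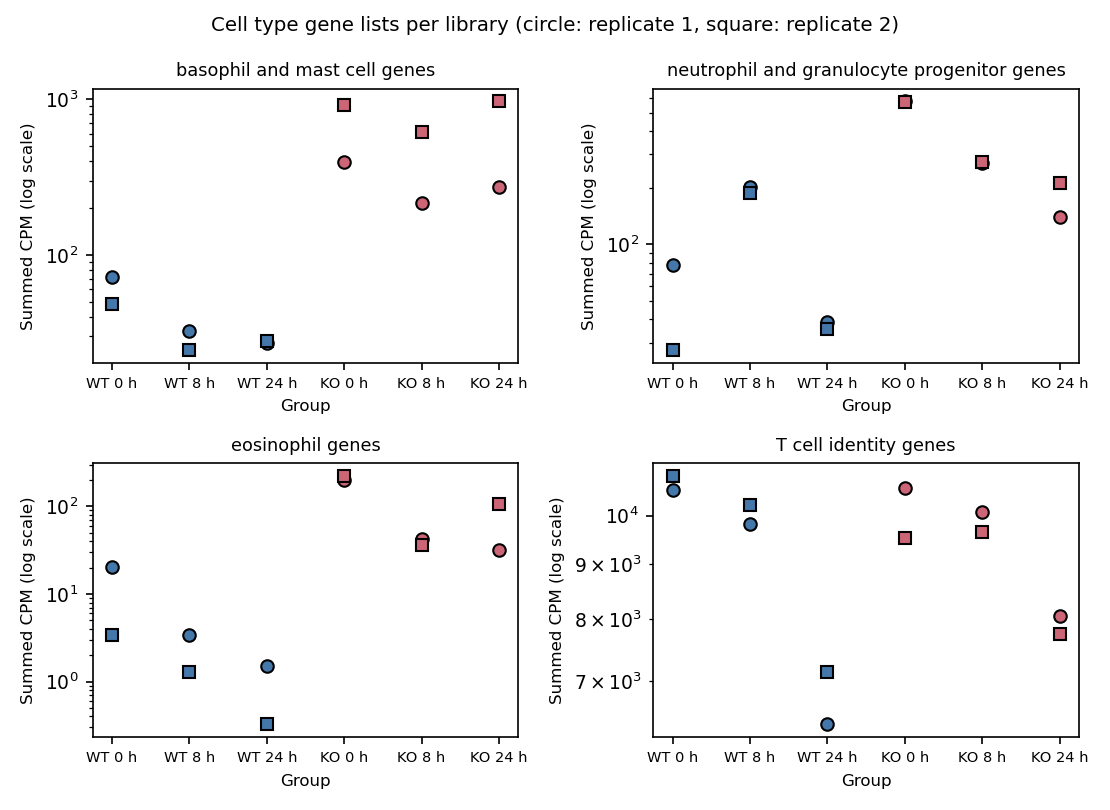
Summed CPM (y axes, log scale) of 4 cell type gene lists in each library, by group (x axes); circles are replicate 1 and squares replicate 2. Basophil and mast cell genes lie between 215.2 and 968.5 in the KO libraries and between 24.4 and 72.5 in the WT libraries. In the panel of neutrophil and granulocyte progenitor genes, Gfi1 alone held 200.1 of 202.3 and 185.4 of 187.3 CPM in the WT 8 h libraries. It held 113.2 of 140.2 and 109.2 of 212.8 CPM in the KO 24 h libraries, so this sum does not follow the other genes of the list at 8 h and 24 h.

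Whether the KO effect itself changed with time was tested as an interaction. The test takes libraries of different times as independent, which the labels do not state. Between 0 h and 24 h it changed for 4194 genes, 1866 upwards and 2328 downwards, and all 46 S phase genes were among the latter (median -3.31; camera adjusted p = 2.28e-43, and 0.0634 with an estimated correlation). Among the named genes Clspn (-7.11 ± 0.45) and Mcm10 (-7.04 ± 0.24) had the largest downward changes, and Pak6 (4.16 ± 0.60) and the ligand gene Wnt3 (3.998 ± 0.877) the largest upward ones. Clspn stood at 2.50 ± 0.36 in KO over WT cells at 0 h and at -4.61 ± 0.28 at 24 h. The change includes the 0 h value, and which cells held that RNA is not shown by these libraries. Between 0 h and 8 h the effect changed for 156 genes, 41 upwards and 115 downwards, with 20 of 46 S phase genes downwards (adjusted p = 0.0634 with an estimated correlation) and the hexokinase gene Hk2 at -2.81 ± 0.28. For Ddx55 the change was -0.59 ± 0.15 from 0 h to 8 h (adjusted p = 0.0768) and -0.56 ± 0.15 from 0 h to 24 h (adjusted p = 0.011). The count from 0 h to 8 h was 92 and 75 without WT 0 h replicate 1 or 2, 48 and 84 without WT 8 h replicate 1 or 2, 317 without KO 0 h replicate 2 and 94 without KO 8 h replicate 2. It was 445 with no filter on low counts, 296 in DESeq2, and 304 and 284 without the 3 KO libraries numbered 1 or 2, the last pair chosen after seeing the data. Averaged over the times, 4119 genes differed between KO and WT, 1925 higher and 2194 lower, and Ddx55 stood at -1.71 ± 0.06.

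Whether the same genes differed at each time was asked by the overlap of the calls, which share no library between times. The expected numbers below assume that libraries of different times are independent, which the labels do not state. Of the genes higher in KO cells, 165 were shared between 0 h and 8 h (13.8 expected by independent draws), 297 between 0 h and 24 h (129.6 expected) and 238 between 8 h and 24 h (53.2 expected). Of the genes lower in KO cells, 10, 60 and 104 were shared (1.2, 34.5 and 24.2 expected). At all 3 times 135 genes were higher and 8 lower, and the former include the p53 targets Cdkn1a, Bbc3, Bax and Zmat3, the progenitor genes Cd34 and Kit and the cytotoxic granule genes Gzmb and Nkg7, named here after their values were seen. The shared calls of both directions fell between 0 h and 8 h to 107, 55, 53 and 88 without WT 0 h replicate 2, WT 8 h replicate 1, WT 8 h replicate 2 or KO 8 h replicate 2. For 0 h and 24 h they fell to 223 and 135 without WT 0 h replicate 1 or 2. For 8 h and 24 h they fell to 97, 105 and 161 without WT 8 h replicate 1, WT 8 h replicate 2 or KO 8 h replicate 2. With no filter on low counts, in DESeq2 and without the 3 KO libraries numbered 1 they rose to 383, 276 and 293 between 0 h and 8 h. For 8 h and 24 h these were 646, 519 and 909. Of the genes higher at 0 h, 210 were lower at 24 h. Across all 15679 genes, which are not independent of each other, the KO effect at 24 h against the WT change from 0 h to 8 h gave r = -0.063 and rho = -0.096, and the KO effect at 8 h against the WT change from 0 h to 24 h gave r = -0.103 and rho = -0.207. The sign of the first r turned with DESeq2 (0.018), with no filter on low counts (0.027) and without WT 0 h replicate 1 (0.011).

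Relative to gene counts, counts at repeats were lower in WT cells at 8 h and 24 h than at 0 h, and at 24 h they were higher in KO than in WT cells. Whether they fell less in KO cells was not tested. Counts at repeats of the 4 classes were 9.99 ± 0.37% of gene counts in WT cells at 0 h, 7.78 ± 0.45% at 8 h and 6.17 ± 0.19% at 24 h, and 9.11 ± 0.97%, 8.08 ± 1.19% and 7.23 ± 0.54% in KO cells. The KO minus WT difference averaged over times was 0.05 on the log2 scale (exact permutation of the genotype within times, two-sided p = 0.574; the smallest p that the arrangements can give is 0.00926). By class it was 0.17 for LINE, 0.09 for SINE, -0.06 for LTR and 0.09 for DNA repeats, and the smallest exact p of the 4 was 0.213 (adjusted p = 0.333). Among 1167 repeat subfamilies, with gene-based scaling, 188 differed between KO and WT cells at 24 h, 161 higher and 27 lower. With factors from the repeats themselves there were 133, 57 higher and 76 lower, as the median of all subfamilies moved from 0.33 to 0.04. At 0 h 7 subfamilies differed (6 higher, 1 lower) and at 8 h 3 (1 higher, 2 lower). The count at 24 h was 101 and 102 without WT 0 h replicate 1 or 2, 107 without WT 8 h replicate 1 or 2, 48 and 43 without WT 24 h replicate 1 or 2, and 34 without KO 24 h replicate 2. At 0 h it was 4 and 3 without WT 0 h replicate 1 or 2 and 2 without KO 0 h replicate 2. At 8 h it was 1, 0 and 1 without WT 8 h replicate 1, WT 8 h replicate 2 or KO 8 h replicate 2. In the edgeR fit without WT 8 h replicate 2 that gave 0, 41 subfamilies had an unadjusted p under 0.05, and DESeq2 with all libraries gave 6.

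The named subfamilies are endogenous retroviruses apart from the DNA transposons Charlie24 and MARE10, which changed in WT cells, and for most of them 1 to 3 loci gave most of the counts. MMTV-int~RLTR3_Mm, of mouse mammary tumour virus, was higher in KO cells at each time (2.44 ± 0.23 at 0 h, 1.41 ± 0.23 at 8 h and 1.82 ± 0.22 at 24 h). At 24 h its counts in KO cells came mostly from a locus overlapping an exon of Coro2a (GRCm38 chromosome 4, 46575144 to 46585044; 26.4 ± 3.22 against 5.94 ± 0.52 CPM in WT), and at 0 h mostly from an intergenic locus on chromosome 12 (92882540 to 92891112; 20.8 ± 6.27 against 3.76 ± 0.98 CPM). At 24 h the chromosome 12 locus stood at 0.76 ± 0.16 in KO and 1.70 ± 0.57 CPM in WT cells. The gene Coro2a, named after its values were seen, was itself higher in KO cells (2.27 ± 0.16 at 0 h, 0.99 ± 0.15 at 8 h and 1.14 ± 0.15 at 24 h). MMERGLN-int~MMERGLN_LTR was higher at 0 h (326.7 ± 83.4 against 75.3 ± 18 CPM) and at 24 h (886.4 ± 154 against 325.1 ± 83.2), with 93.9% of its counts from a locus on chromosome 8 (121832845 to 121841264) that overlaps an exon of Gm20388. MMVL30-int~RLTR6_Mm, the subfamily with the most counts among those named, was lower at 0 h (8326 ± 27.8 against 12950 ± 841 CPM) and 8 h (7246 ± 1190 against 10680 ± 1470), and 39.7% of its counts came from an intergenic locus 3993 bases from Dhx40. ERVB7_1-LTR_MM~MMETn-int was lower at 8 h and at 24 h (38.5 ± 1.70 against 231.8 ± 26.1 CPM), with 92.4% of its counts from a locus in Wiz. At 24 h ERVB4_1-I_MM, ERVB4_1-I_MM~RLTR50A and RLTR11C_MM were also higher, and MMERVK9E_I-int~RLTR9E, MuLV-int, LTR41B and RLTR41C~RLTR6-int lower. MMERGLN-int was higher at 0 h. Loci overlapping an exon of Il21r gave 82.7% of the counts of RLTR11C_MM, an exon of Dhcr7 85.2% of those of LTR41B and an exon of Vmn2r97 74.4% of those of ERVB4_1-I_MM~RLTR50A. These host genes, named after their values were seen, moved the same way at 24 h (Il21r 1.93 ± 0.12, Dhcr7 -1.96 ± 0.15, Vmn2r97 1.14 ± 0.19).

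Some of these calls on repeats were lost when 1 library was left out, with the direction kept. At 0 h MMERGLN-int lost its call (adjusted p = 0.0476) without WT 0 h replicate 1 or 2 (0.602, 0.335), WT 8 h replicate 1 or 2 (0.0865, 0.0874), WT 24 h replicate 1 or 2 (0.057, 0.0565) and KO 0 h replicate 2 (0.139). MMERGLN-int~MMERGLN_LTR lost its call at 0 h without KO 0 h replicate 2 (0.119) or KO 8 h replicate 1 (0.0626), and at 24 h without KO 24 h replicate 2 (0.0641). MMVL30-int~RLTR6_Mm lost it at 0 h without WT 0 h replicate 1 (0.0733), KO 0 h replicate 1 (0.165) or KO 0 h replicate 2 (0.139). At 8 h it did so without WT 8 h replicate 2 (0.406), WT 24 h replicate 1 or 2 (0.0732, 0.0717), KO 0 h replicate 1 or 2 (0.154, 0.201) and KO 8 h replicate 1 (0.152). Without WT 8 h replicate 1, WT 8 h replicate 2 or KO 8 h replicate 2, MMTV-int~RLTR3_Mm (0.211, 0.123, 0.0931) and ERVB7_1-LTR_MM~MMETn-int (0.288, 0.214, 0.29) lost their calls at 8 h. ERVB4_1-I_MM~RLTR50A lost its call at 24 h without WT 8 h replicate 1 or 2 (0.0573, 0.0574), WT 24 h replicate 1 or 2 (0.125, 0.214) and KO 24 h replicate 1 or 2 (0.077, 0.211).

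By position, the median log2 change of subfamilies at 24 h was 0.14 at exonic, 0.40 at intronic and 0.68 at intergenic loci, a split chosen after seeing the data. Summed over the 4 classes, the counts rose by 0.39 at intronic and 0.31 at intergenic loci. In WT cells 508 subfamilies changed from 0 h to 8 h (66 higher, 442 lower) and 735 from 0 h to 24 h (58 higher, 677 lower). The first count was 305 without WT 8 h replicate 1. With factors from the repeats themselves the counts were 375 (175 higher, 200 lower) and 470 (222 higher, 248 lower). ERVB2_1-I_MM~RLTR13D2, with 72.7% of its counts from a locus in Ifi213, went from 459.1 ± 83.4 to 4.08 ± 0.97 CPM by 24 h, and ERVB7_1-LTR_MM~MMETn-int from 7.30 ± 0.70 to 231.8 ± 26.1.

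**Figure D4:**
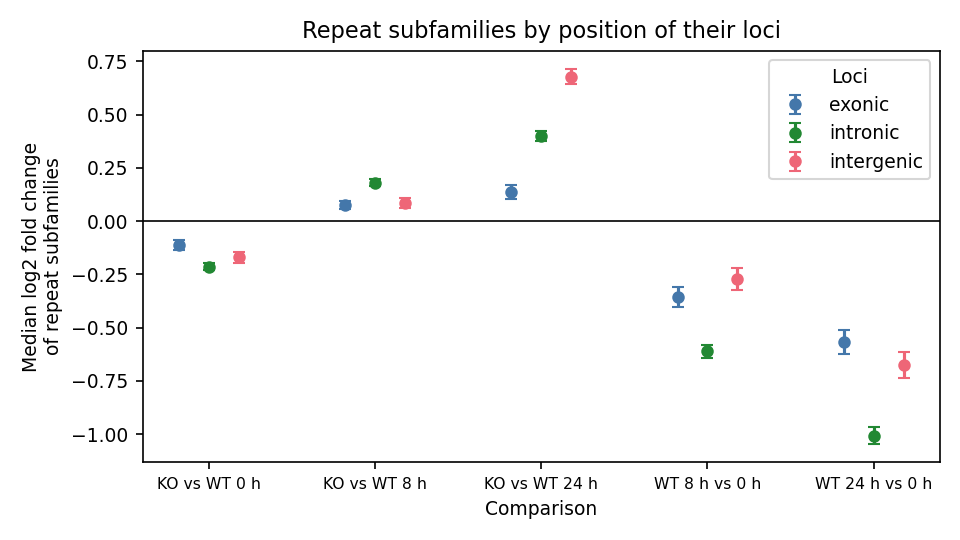
Median log2 fold change of repeat subfamilies (y axis) in 5 comparisons (x axis), counted at exonic, intronic or intergenic loci with gene-based scaling; whiskers show the standard error of the median. At 24 h the KO over WT medians are 0.14, 0.40 and 0.68 in that order.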

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

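The tests on the basophil and mast cell genes, the B cell markers, the T cell identity genes and the intronic repeat loci, and the course position of the G2/M genes, were chosen after the results were seen, and so was the version of the receptor test without genes of many counts.

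The KO effect differed between times by an interaction test, in edgeR for the genes and in camera with the preset correlation for the lists. The test takes libraries of different times as independent, which the labels do not state. The adjusted p of each list with an estimated correlation, which lay above 0.05, stands beside it. Between 0 h and 8 h the effect differed for 156 genes and 22 of the named genes. The changes on the log2 scale were 1.81 for Inka2, 1.64 for Slc19a2, 1.60 for Enc1, 1.46 for Zfp365, 1.44 for Rgs12, -3.07 for Dnph1, -2.81 for Hk2, -2.77 for Spire1, -2.60 for Tnfrsf21 and -2.54 for Wee1. In camera 11 lists passed. Their medians were 0.506 for p53 target genes (adjusted p = 0.281 with an estimated correlation) and 0.13 for cytosolic ribosomal proteins (adjusted p = 0.785 with an estimated correlation). Lower medians were -0.12 for ribosome biogenesis factors (adjusted p = 0.705 with an estimated correlation), -0.85 for S phase genes (adjusted p = 0.0634 with an estimated correlation), -0.84 for G2/M genes (adjusted p = 0.331 with an estimated correlation), -0.49 for replication-dependent histones (adjusted p = 0.351 with an estimated correlation), -0.34 for glycolysis genes (adjusted p = 0.247 with an estimated correlation), -0.17 for nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.623 with an estimated correlation), -0.31 for cholesterol synthesis genes (adjusted p = 0.468 with an estimated correlation), -0.48 for unfolded protein response genes (adjusted p = 0.0634 with an estimated correlation) and -0.14 for repeat silencing and restriction factors (adjusted p = 0.483 with an estimated correlation).

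Between 0 h and 24 h the effect differed for 4194 genes and 124 of the named genes, Ddx55 among them (-0.562). The changes were 4.16 for Pak6, 3.998 for Wnt3, 3.53 for Cyp4f17, 3.48 for Sox4, 3.37 for Cd80, -7.11 for Clspn, -7.04 for Mcm10, -7.04 for Iqgap3, -6.90 for Aunip and -6.77 for Cdc6. In camera 15 lists passed. Their medians were 1.24 for p53 target genes (adjusted p = 0.168 with an estimated correlation), 0.59 for cytosolic ribosomal proteins (adjusted p = 0.523 with an estimated correlation), 0.50 for T cell receptor early response genes (adjusted p = 0.553 with an estimated correlation), 0.42 for naive and quiescence genes (adjusted p = 0.556 with an estimated correlation), 0.93 for T helper lineage genes (adjusted p = 0.168 with an estimated correlation) and 0.34 for ATF4 and amino acid response genes (adjusted p = 0.606 with an estimated correlation). Lower medians were -0.39 for interferon-stimulated genes (adjusted p = 0.705 with an estimated correlation), -3.31 for S phase genes (adjusted p = 0.0634 with an estimated correlation), -4.83 for G2/M genes (adjusted p = 0.176 with an estimated correlation), -2.64 for replication-dependent histones (adjusted p = 0.12 with an estimated correlation), -1.25 for glycolysis genes (adjusted p = 0.162 with an estimated correlation), -0.43 for nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.606 with an estimated correlation), -1.54 for cholesterol synthesis genes (adjusted p = 0.176 with an estimated correlation), -0.48 for unfolded protein response genes (adjusted p = 0.221 with an estimated correlation) and -0.39 for repeat silencing and restriction factors (adjusted p = 0.443 with an estimated correlation).

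Repeat classes outside the 4 tested ones are data that the comparisons leave out. In 7 of 18 values (6 classes at 3 times) both KO libraries had more of these counts than both WT libraries, which chance gives in 16.7% of cases for 1 class. The classes of a time share the same 4 libraries and scaling, so the 7 are not independent of each other. At 0 h 0 of the 6 classes did, and 5 of the 6 ratios lay below 0. The log2 ratios of KO over WT of the 7 were 0.265 for DNA? at 8 h, 0.521 for LTR? at 24 h, 0.535 for Other at 24 h, 0.107 and 0.317 for Satellite at 8 h and 24 h, 0.114 for Unknown at 24 h and 0.142 for scRNA at 24 h. These ratios were not tested.

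Granulocyte and basophil genes were higher in the KO libraries, and 14 of 18 tested basophil and mast cell genes passed the threshold at 24 h. These genes were listed because genes of this kind already led the calls, and 0 of the 18 are on the lists fixed before, so the count restates the pattern and decides nothing about its source. A lower share of T cells would raise the markers of all other cell types alike. The B cell markers had a median of 0.148 (median absolute deviation 2.305) against 5.211 (1.458) for the basophil and mast cell genes. The latter were picked for their high values, so this gap cannot decide on a lower share. Among lists fixed before, B cell markers were higher in 0 and lower in 3 cases at 24 h. Myeloid markers and CD8 T and NK cell markers were each higher in 7 and lower in 0. A lower share of T cells therefore stays open here. Cells of these lineages among the KO cells may be the source and stay open, as does expression of these genes by KO T cells themselves, which was not tested. A purification of naive CD4+ T cells would remove granulocytes and basophils, and its steps are not given in the sources used here.

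S phase and G2/M genes were lower in KO cells at 24 h, by medians of -2.80 and -3.01. The T cell identity genes had a median of 0.207 (median absolute deviation 0.275). This argues against a lower share of T cells as the source of falls as large as these. The same genes fell in WT cells from 0 h to 24 h, with 15 of 19 lower and 4 higher (median -0.991). Weaker activation of KO cells could therefore mask a smaller drop in the share, which stays open. A uniform shift to an earlier point of the WT course was examined in genes that changed by over 2 on the log2 scale from WT 8 h to WT 24 h. Of that change, 1053 other genes had reached a median share of 0.533 and 38 S phase genes 0.15 (difference 0.383 ± 0.036, bootstrap SE). For 38 G2/M genes the share was 0.468, near that of the other genes. The series holds no library between 8 h and 24 h, and a uniform shift could give unequal shares if genes change at different times. The shares therefore cannot decide on such a shift, which stays open for both lists. So does a delay in which genes of different timing lag to different degrees. An effect of Ddx55 loss on entry into S phase, or a p53 checkpoint, may lie behind the pattern, and neither was tested.

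Repeat counts were higher relative to gene counts in KO cells at 24 h, with a median over subfamilies of 0.33 with gene-based factors and 0.04 with factors from the repeats themselves. For DNA carried over into these libraries, the log2 ratio of summed counts of sensory receptor genes was 0.999 at 24 h, but 79.2% of these counts came from Vmn2r97, which has its highest counts at 0 h and an exon that overlaps a locus of the named subfamily ERVB4_1-I_MM~RLTR50A, so that the value does not stand apart from repeat counts. Without the genes of more than 60 counts, a choice made after seeing the data, the ratio was 1.135, from 13.4 and 23.8 CPM in the KO and 7.99 and 8.92 CPM in the WT libraries. For more unspliced RNA the values disagree, since subfamilies rose by a median of 0.399 at intronic and 0.677 at intergenic loci, but the summed counts of the 4 classes by 0.387 and 0.307 and those of LTR repeats by 0.289 and 0.087. Carried-over DNA and unspliced RNA may each account for part of the rise and stay open, as does transcription of repeats in KO cells, which was not tested apart from them.

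For the KO effect averaged over times, 1 of 100 drawn assignments of the genotype within times (108 are possible), the real one, gave as many genes as its 4119. The highest of the others, with 4 libraries moved, gave 3863, so the count need not reflect a difference at every time. The share of 1 in 100 counts against chance only if libraries of different times are independent, which the labels do not state. If KO or WT libraries of a number shared a source, the 4 sources would give 3 splits, too few for a share under 0.05.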

How the results depend on the processing

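The fits of 9 libraries without the KO libraries of either number, and the repeat counts from exonic, intronic or intergenic loci alone, were chosen after seeing the data.

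The numbers of genes past the threshold at 24 h, in both WT comparisons, in the change of the KO effect from 0 h to 24 h and averaged over times stayed within 1.5 times under all alternatives run. Named genes kept direction and side of the threshold in 532 of 534 cases with RLE size factors, 500 of 529 with DESeq2, 508 of 534 without a filter, 523 of 530 with a CPM of at least 1 in 2 libraries, 254 of 307 in fits of 4 libraries and 5982 of 6408 when 1 library was left out. For gene lists these were 236 of 240, 206 of 240, 220 of 240, 232 of 240, 86 of 90 and 2718 of 2880. Where a group keeps 1 library, that library is assumed to vary like the other groups.

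Other counts moved. For KO against WT at 0 h, 464 genes passed in the fit of 4 libraries, which has fewer samples, and 1895 without the KO libraries numbered 2. At 8 h, 862 passed with no filter, 641 with DESeq2 and 1215 without the KO libraries numbered 1. The change of the KO effect from 0 h to 8 h gave 445 with no filter, 296 with DESeq2, and 304 and 284 without the KO libraries numbered 1 or 2. Genes shared between 0 h and 8 h were 383 with no filter, 276 with DESeq2 and 293 without the KO libraries numbered 1, and those shared between 8 h and 24 h 646, 519 and 909. The correlation of the KO effect at 24 h with the WT change from 0 h to 8 h turned to 0.027 with no filter and 0.018 with DESeq2. The cause was not tested.

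The replicate numbers were not taken to pair the libraries. The reason was that only 8 of 15 pairs of groups had r over 0.1 (from -0.10 to 0.288). All 3 pairs among the KO groups did (0.288, 0.222 and 0.111). Among the WT groups r was 0.22, 0.106 and 0.09. Across genotypes r lay between -0.1 and 0.241, and these pairs cannot show whether libraries of a genotype share a source. The basophil and mast cell genes were higher in KO replicate 2 at each time. The values within genotypes are a hint from the data that libraries of a number may share a source within a genotype. The main fit takes all libraries as independent, so its tests across times do not allow for such a source. With the replicate number as a block, 669 genes and 6 repeat subfamilies passed at 8 h, and 274 and 542 genes were shared between 0 h and 8 h and between 8 h and 24 h. Named genes kept direction and side of the threshold in 514 of 534 cases with the block.

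Repeat subfamilies with factors from the repeats themselves gave 14 at 0 h, 5 at 8 h and 470 for WT at 24 h against 0 h. At 8 h no filter gave 5 and DESeq2 6, and at 24 h 125 passed with loci under 10 counts left out. Exonic loci alone gave 20 at 0 h, 12 at 8 h and 476 for WT at 24 h against 0 h. Intronic loci alone gave 1 at 0 h, 0 at 8 h in edgeR (27 at an unadjusted p under 0.05) and 39 at 24 h. Intergenic loci alone gave 170 and 359 for WT at 8 h and 24 h against 0 h. The cause was not tested.

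Named subfamilies turned in sign with part of their loci, which holds fewer counts. With intronic loci these were MMERGLN-int~MMERGLN_LTR (-0.227 at 0 h, -0.068 for WT at 24 h against 0 h), MMERGLN-int (-0.138 at 0 h), MMVL30-int~RLTR6_Mm (0.019 at 8 h), RLTR11C_MM (-0.073 at 24 h) and MMERVK9E_I-int~RLTR9E (0.005 at 24 h), and for WT at 8 h against 0 h RLTR44-int~RLTR44C (-3.614), RLTR48B (-1.067), MLTR13 (-0.941) and IAPEY3_LTR~IAPEy-int (0.871). With exonic loci these were MMERGLN-int (-0.018 at 0 h) and MuLV-int (1.126 at 24 h). With intergenic loci these were MMTV-int~RLTR3_Mm (-0.905), MuLV-int (0.385) and LTR41B (0.413) at 24 h, and for WT at 8 h against 0 h RLTR44-int~RLTR44C (-0.458), BGLII~RMER3D-int (0.994) and RLTR53B_Mm (0.655).

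Gene list medians turned in sign when libraries were left out. At 0 h T cell receptor early response genes stood at -0.259 without WT 0 h replicate 2 (highest 0.509, without WT 0 h replicate 1), oxidative phosphorylation genes at -0.013 without KO 0 h replicate 1 (highest 0.251, without KO 0 h replicate 2), and ATF4 and amino acid response genes at -0.065 without KO 0 h replicate 1 (highest 0.293, without KO 0 h replicate 2) and -0.04 without the KO libraries numbered 1. At 8 h cytosolic ribosomal proteins stood at 0.143 without KO 8 h replicate 2 (lowest -0.177, without KO 8 h replicate 1) and 0.133 without the KO libraries numbered 2, and oxidative phosphorylation genes at 0.066 (lowest -0.206) and 0.056 without the same libraries. For the change from 0 h to 8 h cytosolic ribosomal proteins stood at 0.001 without KO 0 h replicate 2 and -0.033 without KO 8 h replicate 1 (highest 0.289, without KO 0 h replicate 1), and T cell receptor early response genes at -0.128 without WT 0 h replicate 1 (highest 0.446, without WT 0 h replicate 2). Averaged over times cytosolic ribosomal proteins stood at -0.016 without the KO libraries numbered 1 and oxidative phosphorylation genes at 0.026 without those numbered 2.

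Leaving out 1 library at a time, the genes past the threshold ranged from 348 to 1079 at 0 h, 103 to 568 at 8 h and 4202 to 6495 at 24 h, from 8241 to 10036 and 9104 to 10819 for WT at 8 h and 24 h, from 48 to 317 and 3002 to 4401 for the changes of the KO effect, and from 3202 to 4400 averaged over times. Repeat subfamilies ranged from 2 to 10 at 0 h, 0 to 4 at 8 h and 34 to 276 at 24 h, and from 305 to 554 and 512 to 759 for WT. Shared genes ranged from 53 to 206, 135 to 375 and 97 to 465, the correlations from -0.081 to 0.011 and -0.14 to -0.022, and the gene lists past the threshold from 140 to 151. The repeat ratio ranged from -0.004 to 0.097, and by class from 0.095 to 0.245 (LINE), 0.051 to 0.132 (SINE), -0.118 to -0.01 (LTR) and 0.043 to 0.128 (DNA). The 0 at 8 h came without WT 8 h replicate 2 in edgeR (41 at an unadjusted p under 0.05), and the value of -0.004 without KO 8 h replicate 2.

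With 2 libraries per group, 33.8% of genes changed 1.5-fold were recovered at 24 h in simulated data of this depth with 200 changed genes. In the data 6041 genes passed at 24 h, so this share need not carry over to that comparison.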

Other observations

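The values in this part are from lists fixed before the data were examined, with the eosinophil genes as the exception, chosen after the values were seen.

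Further gene lists compared KO with WT cells at 24 h. Genes next to Ddx55 were lower in 2 of 8 cases, Kmt5a at -0.59 ± 0.10 and Eif2b1 at -0.62 ± 0.11 (median -0.26; adjusted p = 0.509 with an estimated correlation). DEAD-box and DEAH-box helicases other than Ddx55 were higher in 7 and lower in 16 of 51 cases (median -0.05; adjusted p = 0.747 with an estimated correlation). Repeat silencing and restriction factors were higher in 4 and lower in 14 of 29 cases, with Uhrf1 at -4.17 ± 0.12 (adjusted p = 0.526 with an estimated correlation). Uhrf1 is also on the list of S phase genes, so its fall is not separate from theirs. Mitochondrially encoded genes were lower in 4 of 12 cases (median -0.34; adjusted p = 0.488 with an estimated correlation). Unfolded protein response genes were lower in 10 and higher in 3 of 20 cases (median -0.26; adjusted p = 0.305 with an estimated correlation). Anti-apoptotic genes were higher in 9 and lower in 3 of 15 cases (median 0.69; adjusted p = 0.195 with an estimated correlation).

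Activation receptors and transporters at 24 h were higher in 13 and lower in 3 of 23 cases (median 0.64; adjusted p = 0.306 with an estimated correlation), naive and quiescence genes higher in 14 and lower in 3 of 30 (median 0.41; adjusted p = 0.556 with an estimated correlation). Memory-like T cell genes were higher in 13 and lower in 2 of 19 cases (median 1.37; adjusted p = 0.331 with an estimated correlation), and interferon-stimulated genes higher in 18 and lower in 7 of 75 (median 0.22; adjusted p = 0.793 with an estimated correlation).

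Markers of other cells at 24 h were higher in 7 of 18 cases for myeloid cells (median 0.60; adjusted p = 0.483 with an estimated correlation), 5 of 9 for regulatory T cells (median 0.65; adjusted p = 0.23 with an estimated correlation), 2 of 9 for erythroid cells and platelets (median 1.16; adjusted p = 0.487 with an estimated correlation) and 1 of 6 for stromal and endothelial cells (median 0.04; adjusted p = 0.634 with an estimated correlation). B cell markers were lower in 3 of 8 cases, with a median of 0.15 and a mean of 0.07 while camera gave a lower direction (adjusted p = 0.782 with an estimated correlation). The summed CPM of the 7 tested eosinophil genes was 200.7 and 224.7 in the KO libraries at 0 h and 20.4 and 3.37 in the WT libraries.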
